A study of Mus musculus with 6 samples.

How the data were processed

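Contacts of chromatin with the nuclear lamina were mapped by DamID in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, of the C57BL/6 strain. In DamID a bacterial adenine methyltransferase (Dam) is fused to a lamin, a filament protein that lines the inner nuclear membrane. Sequence that touches the lamina is methylated at GATC sites, and the methylated fragments are amplified and sequenced. Dam alone, expressed in parallel cells, gives the background that each ratio is set against. Per the labels' protocols, cells received lentiviral shRNA, were selected with puromycin and were then transduced with Dam alone or a Dam fusion, and libraries were made with an NEBNext kit for Illumina sequencing.

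The 6 libraries made 3 maps, each from 1 Dam-only and 1 fusion library. The LmnA RNAi and LmnC RNAi maps were made with Dam-LmnB1, and the LmnB1 RNAi map with Dam-LmnA, per the sample titles. The treatment protocol names shRNA against LmnA or LmnC, and the LmnB1 target was taken from the description labels. Each group holds 1 library, so no test across replicates was possible, no p-value is given and differences are between these maps. RNA and protein were not measured, so the depletion of each lamin could not be checked in these data. A map of cells without shRNA was not analysed here.

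Reads were aligned with Bowtie to the mm9 build of the mouse genome, per the submitters' processing notes, which name no version. Read filters, the ratio step, the LAD caller and its settings are not given in the sources used here. The deposited signal is on a log2 scale, with 1 value for each of 6581229 GATC fragments (median length 257 bp), and the fragments were identical in the 3 maps. From the steps of the deposited values, each is log2 of fusion reads over Dam-only reads, with 1e-05 added to both, plus a constant for the map. The constant was -0.34 for LmnA RNAi, 0.21 for LmnC RNAi and -0.15 for LmnB1 RNAi. A fragment with 0 reads in 1 library therefore has a value near 17 or beyond in either direction, and here any size above 12 was read as such. Reads recovered from these fragments were whole numbers within 0.02 in 100% of values up to 100 reads. A value equal to the constant stands for 0 reads in both libraries or equal reads in both, which the log2 ratio does not separate. All 166253 fragments on unplaced sequences held the constant, and they were left out. The deposited LAD lists give the start and end of each lamina-associated domain (LAD) in bp, with a shortest LAD of 100 kb and a shortest gap of 25.1 kb.

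Total reads per library are unknown, because ratios were deposited. On chromosomes 1 to 19, X and Y, each map had 6414976 fragments. Of these, 30.3% of the LmnA RNAi, 29.2% of the LmnC RNAi and 30.6% of the LmnB1 RNAi fragments held the constant. Fragments read in the fusion library alone made up 16.9%, 13.0% and 14.2%, in that order, and fragments read in the Dam-only library alone 8.25%, 12.0% and 10.2%. These single-library fragments held 3031313, 1914486 and 2035121 fusion reads, and 1442271, 2759812 and 1861546 Dam-only reads. Their median was 1 or 2 reads, so a mean over many fragments is needed for a stable value, and single-library fragments weigh heavily in it because of the small number added before the log. Where only these are left out below, fragments at the constant stay in. They hold 10.5%, 9.63% and 11.1% of fragment length after LmnA, LmnC and LmnB1 RNAi. They pull each mean toward the constant of its map, which differs between maps (-0.34, 0.21 and -0.15). Leaving single-library fragments out drops more fusion-only than Dam-only fragments after LmnA RNAi (16.9% against 8.25%) and near-equal shares after LmnC RNAi (13.0% against 12.0%). It can therefore lower the LmnA RNAi mean by itself.

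Signal was averaged over 100 kb bins, weighting fragments by length, and the 25588 bins with at least 50% of their length covered in all maps were used. The share of the genome in LADs is the share of fragment length (2539 Mb in all) whose fragments have their middle in a LAD. Overlap of 2 LAD lists was measured by the Jaccard index, the bp in both lists over the bp in either, beside 1000 draws in which one list was shifted around each chromosome. A LAD counted as matched when at least 1 bp of it lay in a LAD of the other list. Stretches in a LAD of one map and outside the LADs of another were kept from 100 kb. LAD borders were compared with the nearest border of the same side, and signal was averaged in 10 kb bins up to 200 kb from the borders of LADs of at least 400 kb. Borders shared by all maps were those of the LmnC RNAi map with a border of each other map within 10 kb. Stretches of 10 kb or more without a fragment (170, 23.6 Mb) were treated as assembly gaps.

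Spreads over the 20 chromosomes 1 to 19 and X, 95% intervals from 1000 resamplings of these chromosomes, and standard errors over fragments or borders describe variation along the genome within 1 pair of libraries. They are not replicate error. The spread that fragment sampling gives was measured by splitting each map's fragments into odd-numbered and even-numbered ones and comparing the signal of the 2 sets.

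Regions named in the text followed a rule fixed before the data were examined. They are the 3 longest LADs of each map, the 5 longest stretches per pair and direction, the 5 bins per pair and direction with the largest signal difference, and the chromosomes with the highest and lowest share in LADs. Gene lists fixed at the same time were not used, since no annotation of mm9 was at hand, and regions are given by coordinate.

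Alternatives fixed before the data were examined covered the minimum LAD length, closing of short gaps, other overlap rules, bin sizes, averages, normalizations, autosomes alone, equal coverage of all maps and domains called by one rule for all maps. That rule took 10 kb bins, a running mean, the sign of the mean and runs of at least 100 kb, and its window had not been fixed. A window of 5 bins was run first, on simulated maps and on the deposited signal. Then 5 windows were tried on simulated maps, and 11 bins were kept, after the 5-bin result on the deposited signal had been seen. The simulated pair of maps lay on the real 6414976 fragments, with a log2 ratio of 0.7 inside and -1.2 outside domains. In it, 100 stretches of 300 kb were removed from domains and 100 were added. With 11 bins, 99 removed and 100 added stretches were recovered, and 209 of the 413 stretches called overlapped no planted one. With 5 bins these counts were 96, 91 and 884 of 1113. The true Jaccard index of 0.961 came out as 0.887 with 11 bins and 0.771 with 5. Sampling noise and the rule itself were not separated in this drop, and the simulated reads were not matched to the depth of the real libraries. Assembly gaps removed, fragments with 0 reads in 1 library left out, fragments at the constant left out and the choice of 11 bins over 5 came after seeing the data.

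Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.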

Results

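LADs were mapped in 3 populations of MEFs treated with RNAi against lamin A, lamin C or lamin B1. Lamins A and C are splice products of the Lmna gene, and lamin B1 is the product of Lmnb1. The series asks where the genome meets the lamina when a single lamin isotype is depleted. There were 6 libraries, 1 Dam-only and 1 fusion library per map, and no replicates. The LmnA RNAi and LmnC RNAi maps share the Dam-LmnB1 fusion, so they form the direct comparison of isoforms. The LmnB1 RNAi map was made with Dam-LmnA, so any difference from it joins the targeted lamin and the fusion, which cannot be told apart. Coordinates are in mm9, and genes in these regions are not given.

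LADs covered most of the genome in each map and were most extensive after LmnA RNAi. They held 67.9% of the genome after LmnA RNAi, 58.9% after LmnC RNAi and 59.8% after LmnB1 RNAi. The SD over 20 chromosomes was 6.08, 5.73 and 6.17 percentage points in that order. Reads in single-library fragments leaned to the fusion library after LmnA RNAi (3031313 against 1442271 Dam-only reads). They leaned to the Dam-only library after LmnC RNAi (1914486 against 2759812) and lay between after LmnB1 RNAi (2035121 against 1861546). Whether unequal reads in the libraries of a map set this order of LAD shares was not tested. The lists held 1768, 1807 and 1764 LADs, with a median length of 522 kb after LmnA RNAi (interquartile range 247 to 1175 kb), 449 kb after LmnC RNAi (230.04 to 972 kb) and 498 kb after LmnB1 RNAi (246 to 1014 kb). LADs of at least 1 Mb numbered 523, 439 and 450, and those of at least 5 Mb numbered 34, 24 and 19. LADs of the LmnA RNAi and LmnC RNAi maps span assembly gaps, where those of the LmnB1 RNAi map mostly stop (21.5, 20.8 and 0.287 Mb of gaps inside LADs). With gaps removed from all lists there were 1904, 1930 and 1773 LADs with medians of 489, 425 and 495 kb, and 30, 18 and 19 of at least 5 Mb, so neither the order of LmnA and LmnB1 RNAi in median length nor that of LmnC and LmnB1 RNAi in LADs of at least 5 Mb held.

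The longest LAD of the LmnA RNAi map lay on chromosome X from 55194593 to 68654189 (13.5 Mb). LADs of the LmnC RNAi map covered 90.8% of it, and those of the LmnB1 RNAi map 99.3%. Its mean log2 ratio was 2.17 ± 0.04 after LmnA RNAi, 1.13 ± 0.04 after LmnC RNAi and 1.78 ± 0.04 after LmnB1 RNAi (SE over 35937 fragments), and 0.64, 0.49 and 0.44 without fragments that had 0 reads in 1 library. The other two of its longest LADs were on chromosome 15 from 12309916 to 25290419 and on chromosome 1 from 95726158 to 107511952. All 3 longest LADs of the LmnC RNAi map were on X, the first from 23373505 to 33413442 (10.04 Mb, log2 ratio 2.22 ± 0.04, and 0.74 without such fragments). The longest LAD of the LmnB1 RNAi map was on chromosome 14 from 106855251 to 117294296 (10.4 Mb), with a log2 ratio of 2.06 ± 0.03 there (0.86 without them).

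The chromosomes with the lowest and highest shares in LADs were the same in all 3 maps. Chromosome 11, which is gene-dense, had the lowest share, at 53.2% after LmnA RNAi, 46.2% after LmnC RNAi and 46.4% after LmnB1 RNAi. Among autosomes chromosome 14 had the highest share, at 73.7%, 62.9% and 65.1%. Chromosome X stood above every autosome, at 83.1%, 75.6% and 77.7%. The mean over 19 autosomes was 66.4% (SD 4.94), 57.3% (SD 4.13) and 58.1% (SD 4.48). Of chromosome Y, 2.60 Mb was covered by fragments, and 88.7%, 85.0% and 82.7% of this lay in LADs. The share was higher after LmnA RNAi than after LmnC RNAi on 21 of 21 chromosomes. That difference was largest on chromosome 13 (14.1 percentage points) and smallest on chromosome 7 (3.15).

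**Figure D1:**
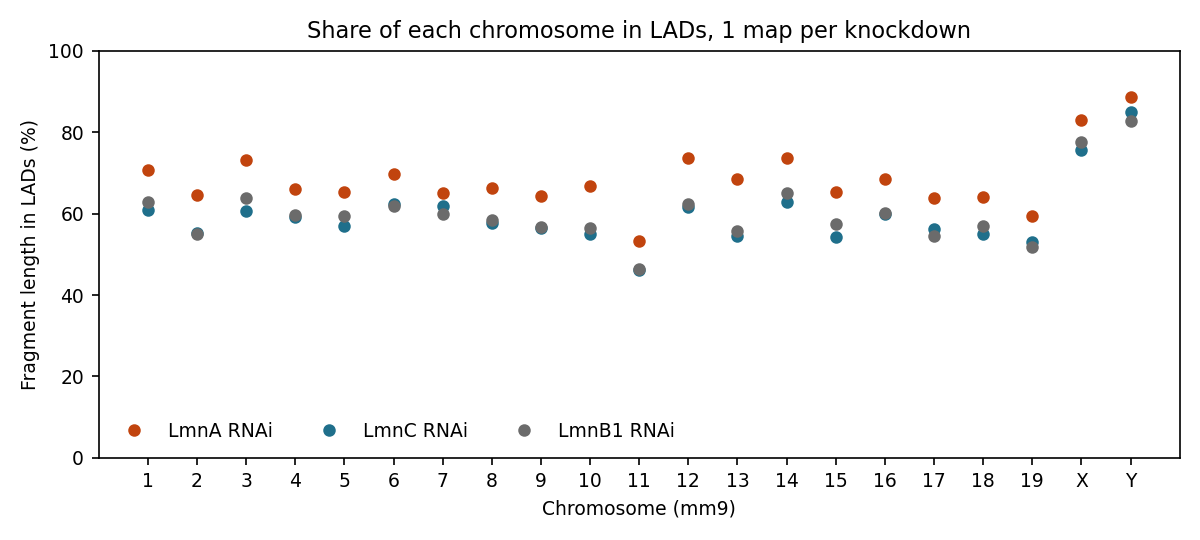
Share of fragment length in LADs (percent, vertical axis) for each mm9 chromosome (horizontal axis), 1 point per knockdown map with no error bars because each map is a single pair of libraries. The LmnA RNAi points lie above the others on all 21 chromosomes, chromosome 11 is lowest (53.2%, 46.2% and 46.4%) and X and Y are highest.

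The LmnA RNAi and LmnC RNAi maps, both made with Dam-LmnB1, were compared for the position of their LADs. LADs of the LmnC RNAi map lay almost wholly within those of the LmnA RNAi map. The lists shared 1492 Mb, which was 97.7% of the LmnC RNAi LADs and 84.8% of the LmnA RNAi LADs. A further 267 Mb was in LADs only after LmnA RNAi, against 35.6 Mb only after LmnC RNAi. The Jaccard index was 0.832 (SD 0.0355 over 20 chromosomes), against 0.450 to 0.496 when one list was shifted along the chromosomes. Of the LmnA RNAi LADs, 303 (17.1%) had no counterpart after LmnC RNAi, and 320 spanned 2 or more LmnC RNAi LADs. In the reverse direction 49 of 1807 LmnC RNAi LADs (2.71%) had no counterpart. With 1 map per knockdown, the spread between replicate maps is unknown, so these differences have no replicate check. Without a map of cells that received no shRNA, sequence in LADs of one map alone cannot be called a gain or a loss.

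Stretches of at least 100 kb in LADs after LmnA RNAi and outside them after LmnC RNAi numbered 802 and made up 222 Mb. Whole LADs accounted for 303 of them, stretches at LAD edges for 347, and sequence between neighbouring LmnC RNAi LADs for 152. The longest was a whole LAD on chromosome 3 from 38798830 to 40960732 (2.16 Mb), where the log2 ratio was 0.36 ± 0.06 after LmnA RNAi, -1.51 ± 0.07 after LmnC RNAi and -0.34 ± 0.06 after LmnB1 RNAi (SE over 5266 fragments). These were -0.06 ± 0.03, -0.84 ± 0.02 and -0.32 ± 0.02 without fragments that had 0 reads in 1 library, so the sign after LmnA RNAi turned. That filter drops more fusion-only than Dam-only fragments from the LmnA RNAi map, so the turn may come partly from the filter. A LAD on chromosome 14 from 99544129 to 101450517 (1.91 Mb) had 0.33 ± 0.07 after LmnA RNAi and -1.56 ± 0.07 after LmnC RNAi (-0.11 and -0.83 without such fragments). On chromosome 3 from 146530492 to 148282824 (1.75 Mb), the values were 0.97 ± 0.07 and -1.57 ± 0.07 (0.17 and -0.85 without them). On chromosome 15 from 34479717 to 35786066 (1.31 Mb), they were 0.64 ± 0.08 and -1.83 ± 0.09 (0.00 and -0.95 without them). A stretch at a LAD edge on chromosome 12 from 95289241 to 96703162 (1.41 Mb) had 0.53 ± 0.10 and -0.99 ± 0.10 (0.02 and -0.46 without them), and 99.8% of it was in LADs after LmnB1 RNAi. Across the 802 stretches the median log2 ratio was 0.42 after LmnA RNAi and -1.33 after LmnC RNAi, and -0.11 and -0.70 without fragments that had 0 reads in 1 library. The ratio was higher after LmnA RNAi in 799, and in 704 once each map was centred on its median bin. These stretches were picked from the LAD lists, so their signal is not independent evidence of a difference.

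**Figure D2:**
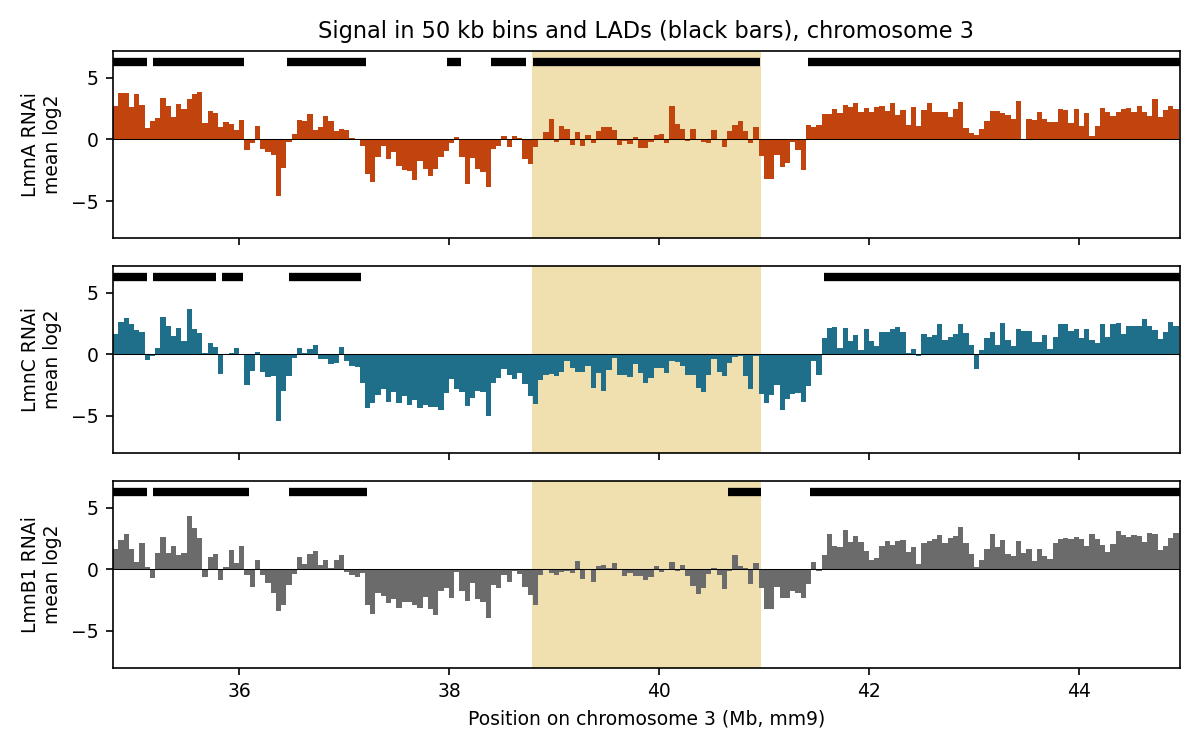
Mean log2 ratio of fusion over Dam-only reads in 50 kb bins (vertical axes) along chromosome 3 (Mb, mm9), 1 panel per knockdown map, with LADs as black bars and the stretch from 38798830 to 40960732 shaded. The stretch is 1 LAD after LmnA RNAi (mean 0.36) and outside LADs after LmnC RNAi (mean -1.51), while LADs cover 14.1% of it after LmnB1 RNAi (mean -0.34). The panels include fragments that had 0 reads in 1 library, and without them the means are -0.06, -0.84 and -0.32.

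Stretches in the other direction were few and short. LADs of the LmnC RNAi map held 96 stretches (16.5 Mb) outside the LmnA RNAi LADs. The longest was on chromosome 2 from 92709032 to 93292883 (0.584 Mb), with a log2 ratio of -1.01 ± 0.14 after LmnC RNAi and -0.65 ± 0.12 after LmnA RNAi (-0.64 and -0.52 without fragments that had 0 reads in 1 library). A whole LAD on chromosome 19 from 6384686 to 6913286 (0.529 Mb) had -0.81 ± 0.22 after LmnC RNAi and -1.46 ± 0.20 after LmnA RNAi (-0.53 and -0.78 without them). The ratio was higher after LmnC RNAi in 28 of the 96 stretches as deposited, and in 90 after centring each map. These stretches too were picked from the LAD lists, so the count after centring is not independent evidence of a difference.

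Signal along the genome followed the same course in the LmnA RNAi and LmnC RNAi maps (Pearson r = 0.951, Spearman rho = 0.942 over 25588 bins of 100 kb, which are not independent replicates). Odd-numbered against even-numbered fragments gave r = 0.926 between the maps, and 0.952 and 0.960 within the LmnA RNAi and LmnC RNAi maps. The LmnA RNAi signal lay above the LmnC RNAi signal by a median of 0.95 on the log2 scale. It was higher by more than 0.5 in 76.2% of bins and lower by more than 0.5 in 0.813%. Centring each map on its median bin turned this split to 16.4% higher and 32.1% lower, and quantile normalization gave 19.4% and 20.4%. Both remove any offset between the maps, so these splits describe bins relative to the rest of their map. Without fragments that had 0 reads in 1 library, 21.7% of bins were higher and 0.0743% lower, with a median difference of 0.27. Over all fragments, the step of 0.5 is close to the SD of 0.45 estimated from fragment sampling for the difference of the 2 maps in a bin. The estimate combines the odd-to-even spread of each map as if independent, and was not measured on the difference itself. Without fragments that had 0 reads in 1 library that SD is 0.16. The 5 bins with the largest excess after LmnA RNAi were all on X, the first from 6000001 to 6100000 (-1.83 ± 0.42 against -6.16 ± 0.62, and -1.26 against -2.16 without fragments that had 0 reads in 1 library). Of the 1% of bins with the largest difference in either direction after centring, 26.7% were on X, and 5.88% without such fragments, where X holds 6.33% of all bins. The bin with the largest deficit was on chromosome 11 from 82600001 to 82700000 (-2.70 ± 0.43 against -1.13 ± 0.31, and -1.61 against -0.89 without them).

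The LmnA RNAi and LmnB1 RNAi maps differed in target and fusion alike. Their LAD lists overlapped about as much as those of the LmnA RNAi and LmnC RNAi maps, with a Jaccard index of 0.830 (SD 0.0283 over 20 chromosomes), against 0.452 to 0.503 for shifted lists. They shared 1492 Mb, which was 84.8% of the LmnA RNAi LADs and 97.4% of the LmnB1 RNAi LADs. Of the LmnA RNAi LADs 314 had no counterpart after LmnB1 RNAi, against 43 of 1764 in the reverse direction. The LAD share was higher after LmnA RNAi on 21 of 21 chromosomes, by 5.20 (chromosome 7) to 12.6 percentage points (chromosome 13).

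Stretches in LADs after LmnA RNAi and outside them after LmnB1 RNAi numbered 810 (222 Mb), and the reverse 103 (16.3 Mb). Of the first kind, 16.8 Mb lay in assembly gaps, against 0.979 Mb of the LmnA RNAi stretches outside LmnC RNAi LADs. The longest of the first kind, on chromosome 7 from 39356195 to 46356194, holds no GATC fragment and thus no signal in any map. The second longest, on chromosome 8 from 19783129 to 22038713, is mostly such a gap and had 578 fragments. The chromosome 14 LAD from 99544129 to 101450517, named above, was also outside LADs after LmnB1 RNAi, with a log2 ratio of -0.35 ± 0.06 there (-0.33 without fragments that had 0 reads in 1 library). In the reverse direction, a stretch on X from 139917997 to 140264844 (0.347 Mb) bridged LADs after LmnB1 RNAi, with -0.46 ± 0.21 against -1.67 ± 0.28 after LmnA RNAi and -2.53 ± 0.24 after LmnC RNAi (-0.41, -0.75 and -0.99 without them). A stretch on chromosome 14 from 103051196 to 103499615 (0.448 Mb) had 0.06 ± 0.13 after LmnB1 RNAi and -0.07 ± 0.14 after LmnA RNAi, a difference within these errors (-0.25 and -0.26 without them).

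Bin signals of the LmnA RNAi and LmnB1 RNAi maps correlated with r = 0.943 and rho = 0.924, and with r = 0.916 between odd-numbered and even-numbered fragments. As deposited, 48.8% of bins were higher after LmnA RNAi by more than 0.5 and 8.47% lower, and after centring these were 14.4% and 32.9%. They were 16.2% and 2.45% without fragments that had 0 reads in 1 library. The largest excess after LmnA RNAi was on chromosome 1 from 188300001 to 188400000 (1.31 ± 0.35 against -2.35 ± 0.39, and 0.02 against -0.86 without such fragments). The largest excess after LmnB1 RNAi was on X from 140000001 to 140100000 (0.06 ± 0.41 against -2.98 ± 0.56, and -0.15 against -0.89 without them).

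The LmnC RNAi and LmnB1 RNAi maps were the closest pair, although target and fusion differed here too. Their Jaccard index was 0.867 (SD 0.0190 over 20 chromosomes, shifted lists 0.403 to 0.464). They shared 1420.5 Mb, which was 93.0% of the LmnC RNAi LADs and 92.8% of the LmnB1 RNAi LADs. A counterpart was lacking for 139 LmnC RNAi LADs and for 124 LmnB1 RNAi LADs. The LAD share was higher after LmnC RNAi on 6 of 21 chromosomes, and the differences ran from -3.20 percentage points (chromosome 3) to 2.27 (Y).

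Stretches in LADs after LmnC RNAi and outside them after LmnB1 RNAi numbered 322 (75.5 Mb), of which 16.1 Mb lay in assembly gaps. The longest with full fragment cover was a LAD on chromosome 6 from 148184171 to 149253294 (1.07 Mb). Its log2 ratio was -0.34 ± 0.08 after LmnC RNAi and 0.01 ± 0.08 after LmnB1 RNAi (-0.28 and -0.07 without fragments that had 0 reads in 1 library), so it was a LAD in the map with the lower deposited signal. In the reverse direction there were 333 stretches (75.9 Mb). The longest were one on chromosome 12 from 95289241 to 96700928 and one on chromosome 5 from 11959749 to 13104612 (1.14 Mb, 0.38 ± 0.09 after LmnB1 RNAi against -0.67 ± 0.10 after LmnC RNAi, and -0.01 against -0.44 without such fragments). A whole LAD on chromosome 14 from 77818415 to 78664932 (0.847 Mb) had -0.13 ± 0.09 against -1.29 ± 0.10 (-0.28 against -0.71 without them). A whole LAD on chromosome 13 from 102539376 to 103334961 (0.796 Mb) had 0.14 ± 0.10 against -1.47 ± 0.12 (-0.15 against -0.75 without them). One on chromosome 8 from 70767968 to 71535386 (0.767 Mb) had -0.09 ± 0.11 against -1.45 ± 0.10 (-0.31 against -0.76 without them).

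Bin signals of the LmnC RNAi and LmnB1 RNAi maps had r = 0.964 and rho = 0.949, and r = 0.939 between odd-numbered and even-numbered fragments. As deposited, 4.74% of bins were higher after LmnC RNAi by more than 0.5 and 51.3% lower, and after centring these were 19.9% and 24.6%. Leaving out fragments that had 0 reads in 1 library gave 0.625% and 9.97%. The bin with the largest deficit after LmnC RNAi was on X from 166300001 to 166400000 (-6.72 ± 0.60 against -3.04 ± 0.51, and -2.66 against -1.76 without such fragments). The largest excess was on chromosome 17 from 31600001 to 31700000 (-0.71 ± 0.28 against -2.39 ± 0.41), and without such fragments it did not hold (-0.83 ± 0.13 against -0.62 ± 0.11).

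LADs of the 3 maps together spanned 1816 Mb, and 77.3% of this (1403 Mb) was in LADs of all maps. A further 10.8% was in LADs of 2 maps and 11.99% in those of 1 map. Most of the latter belonged to the LmnA RNAi map, with 178 Mb, against 18.0 Mb for LmnC RNAi and 21.8 Mb for LmnB1 RNAi. LADs of all but the LmnA RNAi map held 17.6 Mb, of all but LmnC RNAi 88.7 Mb and of all but LmnB1 RNAi 89.05 Mb. The last length includes assembly gaps, where LADs of the LmnB1 RNAi map mostly stop. Counted as fragment length, these classes held 17.5, 88.0 and 68.3 Mb. Grouping sequence by the LAD lists of the same maps builds in a higher signal inside LADs, so the order of group means is not independent evidence. Sequence in LADs of all maps had mean log2 ratios of 2.32, 1.53 and 1.78 after LmnA, LmnC and LmnB1 RNAi. Sequence in LADs of the LmnA RNAi map alone lay lower, at 0.31, -1.59 and -0.87, and still above sequence in no LAD (-2.06, -3.15 and -2.18). Without fragments that had 0 reads in 1 library, sequence in LADs of the LmnA RNAi map alone had -0.20, -0.83 and -0.53, so the sign after LmnA RNAi turned, between 0.96, 0.69 and 0.65 in LADs of all maps and -1.28, -1.52 and -1.14 in no LAD. Here too the turn may come partly from the filter, which drops more fusion-only than Dam-only fragments from the LmnA RNAi map.

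**Figure D3:**
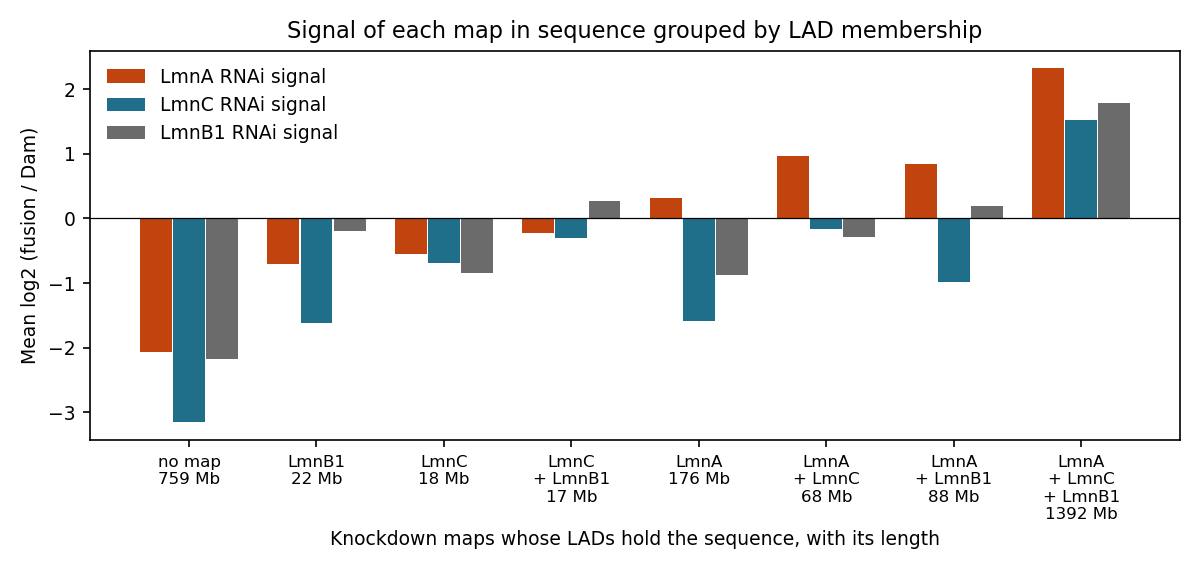
Mean log2 ratio of fusion over Dam-only reads (vertical axis, bars from 0, 1 colour per map) in sequence grouped by the knockdown maps whose LADs hold it (horizontal axis, with the length of fragments in Mb). Sequence in LADs of all maps has the highest mean in each map (2.32, 1.53 and 1.78), and sequence in LADs after LmnA RNAi alone lies between it and sequence outside LADs. The groups come from the LAD lists of the same maps, so this order is not independent evidence. The bars include fragments that had 0 reads in 1 library, and without them the LmnA RNAi mean of that sequence is -0.20 in place of 0.31.

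Distances between LAD borders depended on the LADs included. The median distance from a border after LmnA RNAi to the nearest one after LmnC RNAi was 29.6 kb, and to the nearest after LmnB1 RNAi 37.7 kb. From LmnC RNAi to LmnB1 RNAi borders it was 21.5 kb. Among LADs of at least 400 kb these medians were 55.1, 57.2 and 27.0 kb. Within 10 kb lay 32.4%, 29.9% and 36.4% of borders, and within 50 kb 57.0%, 53.5% and 61.7% (all LADs). At the 370 borders shared by all maps, the log2 ratio between 100 and 200 kb inside exceeded that outside by 3.10 ± 0.11 after LmnA RNAi, 3.34 ± 0.11 after LmnC RNAi and 2.80 ± 0.09 after LmnB1 RNAi (SE over borders). From 25% to 75% of this step the mean profile took 11.8, 11.02 and 11.7 kb, about 1 bin of 10 kb. These borders were picked from the LAD lists of the same maps, so a step up is built in and only its size is described. Over fragments without 0 reads in 1 library, the steps were 1.62 ± 0.05, 1.61 ± 0.05 and 1.27 ± 0.04.

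**Figure D4:**
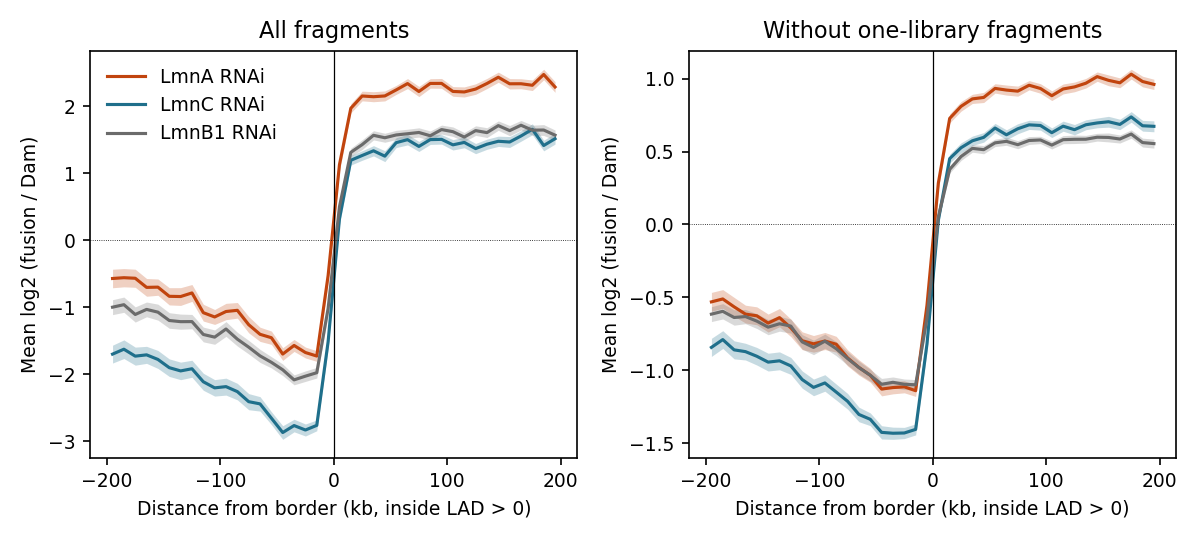
Mean log2 ratio of fusion over Dam-only reads (vertical axes) in 10 kb bins from 200 kb outside to 200 kb inside (kb, horizontal axes) the 370 LAD borders shared by the 3 maps, with the SE over borders as a band; the left panel has all fragments and the right panel leaves out those with 0 reads in 1 library. Each map steps up at the border, by 3.10, 3.34 and 2.80 on the left, and the LmnC RNAi profile is lowest outside. The borders were picked from the LAD lists of these maps, so a step up is built in.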

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

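Of 178 alternative values of 43 results, 64 stayed within the interval of the reported value, or within 1.5 times it for a count, and 114 moved beyond it. These intervals come from the number of bins, LADs or chromosomes along the genome and are not replicate error, so a small move can pass them. No paired analysis was possible because each group has 1 sample, and leaving out a replicate was not possible for the same reason. Assembly gaps removed, the fragment filters and the fragment filter with centring were chosen after seeing the data. For domains called by one rule, neither window had been fixed beforehand. The 5-bin window was run first, and 11 bins were kept after the 5-bin result on the deposited signal had been seen. The order LmnA RNAi above LmnB1 RNAi above LmnC RNAi in genome share held in every list tried except the upper part of LADs by mean signal, where LmnC RNAi lay above LmnB1 RNAi. Among LAD overlaps the LmnC to LmnB1 RNAi index was the highest under each setting. Centring and quantile normalization remove any offset between maps, so their shares of higher and lower bins do not bear on its direction. Without one-library fragments and without centring, the side with more bins was that of the deposited signal in all 3 pairs. Causes were not tested, except where the setting by its construction drops LADs, stretches or bins. Depth limits single fragments most, with a median of 1 or 2 reads where only 1 library was read.

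Genome shares and median lengths below are in the order LmnA, LmnC and LmnB1 RNAi, and Jaccard indices and correlations are for LmnA to LmnC, LmnA to LmnB1 and LmnC to LmnB1 RNAi. Keeping only LADs of at least 200 kb gave shares of 66.1%, 56.8% and 58.0%, medians of 682, 591 and 625 kb, Jaccard indices of 0.822, 0.824 and 0.858, and 76.1% of the union in all maps. Closing gaps of up to 50 kb gave medians of 606, 513 and 577 kb. Domains called by one rule with 11 bins gave shares of 65.1%, 50.3% and 56.5%, medians of 440, 390 and 390 kb, indices of 0.771, 0.857 and 0.873 and 76.0% of the union in all maps. The 5-bin window, which was run first, gave shares of 62.3%, 48.0% and 54.0%, medians of 330, 300 and 290 kb, indices of 0.765, 0.844 and 0.861 and 74.5% of the union in all maps. Under both windows the lowest index was that of LmnA and LmnC RNAi, where the deposited lists put LmnA and LmnB1 RNAi level with it. LmnA and LmnC RNAi also differed most in domain length under both windows (1674.6 and 1293.4 Mb with 11 bins), which caps their index. The lower index therefore need not mean that domain positions differ most. At equal coverage LmnA to LmnC and LmnA to LmnB1 RNAi were level (0.906 and 0.907). LADs in the upper part of each list by mean signal gave 884, 903 and 882 LADs, shares of 51.7%, 43.4% and 42.9% and medians of 945, 779 and 772 kb. Autosomes alone gave shares of 66.8%, 57.7% and 58.6% and 76.6% of the union in all maps. Equal coverage gave indices of 0.906, 0.907 and 0.921 and 87.0% of the union in all maps. Removing assembly gaps moved the LmnA to LmnB1 index to 0.839, the LmnC to LmnB1 index to 0.878 and the union in all maps to 78.2%, and it gave medians of 489, 425 and 495 kb. LADs of at least 5 Mb, 34, 24 and 19 as deposited, numbered 30, 18 and 19 without gaps, 43, 29 and 30 with gaps of up to 50 kb closed, 37, 12 and 25 by one rule with 11 bins and 9, 5 and 10 with 5, so the order of LmnC and LmnB1 RNAi turned in each of these. That order held in the upper part of LADs by mean signal (34, 23 and 19) and with only LADs of at least 200 kb kept (34, 24 and 19).

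When 50% of a LAD had to be covered, the matched shares were 78.3% LmnA to LmnC, 77.9% LmnA to LmnB1, 90.9% LmnC to LmnB1 and 90.9% LmnB1 to LmnC, and the other two directions moved within their interval. A reciprocal 50% gave 66.5% LmnA to LmnC, 65.1% LmnC to LmnA, 64.1% LmnA to LmnB1, 64.3% LmnB1 to LmnA, 70.7% LmnC to LmnB1 and 72.4% LmnB1 to LmnC. Stretches in LADs of the first map named and outside those of the second numbered, from 200 kb up, 397 LmnA to LmnC, 23 LmnC to LmnA, 383 LmnA to LmnB1, 20 LmnB1 to LmnA, 101 LmnC to LmnB1 and 130 LmnB1 to LmnC. From 50 kb up they numbered 214 LmnC to LmnA, 248 LmnB1 to LmnA, 589 LmnC to LmnB1 and 562 LmnB1 to LmnC. Border distances among LADs of at least 400 kb had medians of 55.1, 57.2 and 27.0 kb. Taken over the whole span of the chromosome, the share of X in LADs after LmnB1 RNAi moved to 75.5%.

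Correlations were 0.819, 0.794 and 0.827 in 10 kb bins, 0.969, 0.967 and 0.982 in 1 Mb bins, 0.871, 0.867 and 0.917 with medians and 0.963, 0.958 and 0.978 without fragments that had 0 reads in 1 library. Unweighted means gave 0.939 for LmnA to LmnC and 0.930 for LmnA to LmnB1 RNAi. The share of bins higher by more than 0.5 in LmnA RNAi and in LmnC RNAi was 19.4% and 20.4% after quantile normalization, 16.4% and 32.1% after centring, 21.7% and 0.0743% without one-library fragments, and 2.92% and 6.96% with both changes. The share of bins higher by more than 0.5 in LmnA RNAi and in LmnB1 RNAi was 21.9% and 21.8% after quantile normalization, 14.4% and 32.9% after centring, 16.2% and 2.45% without one-library fragments, and 2.34% and 14.2% with both changes. The share of bins higher by more than 0.5 in LmnC RNAi and in LmnB1 RNAi was 17.6% and 17.5% after quantile normalization, 19.9% and 24.6% after centring, 0.625% and 9.97% without one-library fragments, and 3.53% and 2.99% with both changes.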

Other observations

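The tests of chromosome X, of the closeness of the LmnC RNAi and LmnB1 RNAi lists and of assembly gaps in the stretches between them, and the interval over stretches, were chosen only after related values had been seen, and X was noticed first among the named bins.

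Assembly gaps were treated differently in the deposited lists. All 6 gaps of at least 0.5 Mb, such as that on chromosome 7 from 39356170 to 46356326, lay wholly inside LADs of the LmnA RNAi and LmnC RNAi maps and at most 0.0684% inside those of the LmnB1 RNAi map. In all, 21.5 Mb, 20.8 Mb and 0.287 Mb of gaps were counted as LAD after LmnA, LmnC and LmnB1 RNAi. Of the length of stretches in LmnC RNAi LADs and outside LmnB1 RNAi LADs, 21.3% lay in such gaps, between the bounds of 10% and 50% that would have decided whether gaps account for them. GATC fragments were denser in LADs of all maps, at 261 per 100 kb, than in sequence in no LAD, at 241.

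LADs covered 1759 Mb after LmnA RNAi and 1528 Mb after LmnC RNAi, and 99.7% of the difference of 231 Mb remained without assembly gaps. Gaps were of near-equal length in the 2 lists (21.5 and 20.8 Mb), so this result was set in advance. That length is also too small to account for the difference. A different cut on one shared ranking of bins stays open. At equal coverage the Jaccard index between odd-numbered and even-numbered fragments of the 2 maps was 0.890, against 0.922 and 0.927 within them. It lay below the lower within-map index by 0.032 (95% interval 0.027 to 0.037), past the bound fixed beforehand as counting against this explanation. That bound cannot decide it, because the within-map indices carry sampling noise of 1 library pair alone. Fragments with 0 reads in 1 library stay open too: without them the stretches in LmnA RNAi LADs and outside LmnC RNAi LADs exceeded all bins by a median of 0.31 on the log2 scale (interval 0.28 to 0.33 over resampled stretches), but these were picked from lists made with the same reads. The depleted isoform and variation between single cultures or libraries both stay open, untested without replicates. Unequal reads in the fusion and Dam-only libraries of a map were not tested as a cause either.

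The LmnC RNAi and LmnB1 RNAi lists overlapped more than either did with the LmnA RNAi list. Wider coverage after LmnA RNAi is argued against as the whole cause, because with the same number of bins taken in each map their index of 0.921 still exceeded the higher of the others by 0.0136 (interval 0.0095 to 0.0177). The interval covers chromosomes of these maps and not replicates. Target and fusion change together in this pair, and no biological explanation was tested.

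Among the 1% of bins with the largest centred difference between the LmnA RNAi and LmnC RNAi maps, 26.7% (68 of 255) were on X, which holds 6.33% of bins. Without fragments that had 0 reads in 1 library the share on X was 5.88% (15 of 255), so thin coverage of X may be the source of these bins. That filter keeps fragments at the constant, which held 17.3% of LmnA RNAi fragment length on X and 10.0% on autosomes. Part of the fall may come from these fixed values, so the fall cannot decide the source. On X 42.3% of LmnA RNAi fragments held the constant of the map, against 29.4% on autosomes, and 31.9% against 45.4% had unequal reads in both libraries. Fragments read in 1 library were 25.8% and 25.1% of fragments, but 17.7% and 11.2% of fragment length, which sets their weight in a bin. No biological explanation was tested.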
